A study of Sus scrofa with 6 samples.

How the data were processed

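The series compared brain tissue of 3 wild boars and 3 Rongchang pigs, a Chinese domestic breed. All 6 animals were labelled female and 2 years old. The wild boar libraries were labelled as brain and the domestic pig libraries as cerebrum, and the series title names the prefrontal cortex. Per the labels, the domestic pig libraries were re-analysed ones from an earlier deposit. Breed, source project and labelled tissue therefore separated the same 3 libraries from the other 3, and no fit could part them.

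Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was depleted, and stranded libraries were made from fragmented RNA. Depletion without poly(A) selection keeps circular RNAs (circRNAs), closed loops formed when a downstream splice donor joins an upstream acceptor, as well as unspliced nuclear RNA. The submitters' processing notes name STAR 2.6.0c and BWA 0.7.17 without their roles. The genome build, annotation, circRNA caller and strand setting were not given in the sources used here.

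The authors deposited length-scaled abundance (TPM) for protein-coding genes and TPM for circRNAs, each as a table with 1 column per library, and 0 further columns of per-sample values went unused. The gene table held 21280 genes, and 14821 of their identifiers matched a symbol. Its deposited TPM summed to between 17.17% and 40.88% of 1000000 per library, so the scale was taken over a larger set of transcripts, and a change in the rest of that set moves every listed gene. TPM keeps no depth for genes.

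For circRNAs, depth could be recovered. Each deposited circRNA TPM was a whole number of back-splice reads divided by the circRNA's length and multiplied by 1 factor per library. All 11375 circRNAs came out whole in every library within a relative tolerance of 1e-05, with a largest deviation of 5.61e-07. The reads given are the smallest whole solution with at least 3 reads in 1 library. A factor shared by all 6 libraries cannot be seen. For 11059 circRNAs the smallest whole solution itself reached 3 reads in at least 1 library, so their reads are a lower bound. For 316 it stayed under 3 reads, so the reads given were raised to reach 3 and may exceed the true number. On 2000 simulated circRNAs, each given at least 3 reads in 1 library, the recovery was exact for 98%. Recovered back-splice reads per library were 38047, 59343 and 33644 in wild boar 1 to 3 and 71183, 48822 and 73089 in domestic pig 1 to 3. A count of 0 allows up to 3 reads, or 0.0041% to 0.0089% of a library's back-splice reads, for counting error only.

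Positions of circRNAs are those of the deposited table with the start raised by 1 to count from 1. Host genes were assigned by position with gene names of the Sscrofa11.1 RefSeq annotation. Of the circRNAs, 99.31% lay inside a gene, against 47.24% after a shift of 1000000 bases, and 37 had several candidate hosts.

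Genes were tested at TPM of at least 1 in at least 3 libraries (11752 genes), on log2(TPM + 1). CircRNAs were tested when above 0 in at least 3 libraries (9709), on log2(TPM + 0.045), the value of about 1 read. Fold changes are on these scales and understate changes of low values. Both used limma 3.58.1 with a mean-variance trend in R 4.3.3, wild boar against domestic pig, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Library totals were compared with exact two-sided permutation tests, which cannot go below p = 0.1 with 3 against 3. Gene lists fixed before the data were examined (38 lists, 34 with at least 5 tested members) were tested with limma's camera at a preset inter-gene correlation, with camera at an estimated correlation and with fry beside it. For circRNAs 16 lists were tested by host gene.

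As median-ratio rescaling between libraries moved the median log2 fold change of all genes from -0.41 to 0.00, results are given on deposited and on rescaled TPM, with the scaling named. The log2 factors were -0.18, -0.80 and 0.22 in wild boar 1 to 3 and -0.19, 0.50 and 0.45 in domestic pig 1 to 3.

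Named genes were chosen by a rule written beforehand. It took genes with a symbol, an adjusted p under 0.05, a mean TPM of at least 5 in the higher group and no overlap between the groups' values, up to 12 per direction by fold change. For each list described, it took the 4 tested members of the lowest p. The rule was applied to both scalings. For circRNAs it took 8 per direction, above 0 in all 3 libraries of the higher group, and the 10 of highest mean TPM; where fewer than 3 passed, the 3 of the lowest unadjusted p were taken and said to have missed the threshold.

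The tests were checked on simulated data with the spread of the real values. For genes on deposited TPM, 7% of changes of 1 log2 unit and 87% of changes of 2 units were recovered; after rescaling, 74% and 97%. For circRNAs, 0% of changes of 1 or 2 units, 53% of changes of 3 and 81% of changes of 4 units were recovered. Changes were placed only in genes or circRNAs above a low cutoff of mean value. The noise was normal on the log scale and independent, without read counts or shared shifts of a library. Recovery can therefore differ in the real data, and be lower above all for circRNAs of few reads. The real circRNAs of RASA2 and PLA2R1 passed at log2 -1.15 and -1.71, so the simulated 0% does not carry over to the real values. Of the 34 lists, 0 were called with no list changed, but simulated genes varied independently, and on the real values the 9 other splits of the libraries called 3 to 10 lists, so that check does not cover correlated genes.

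Alternatives covered pseudocounts, filters, scalings, array weights, the trend, a replicate block, leaving out each library, per-host sums, thinning of reads, and limma's voom on recovered reads. The planned negative binomial count tests on recovered reads were not run, and voom on those reads was run in their place. Libraries of 1 group were not copies of each other: over circRNAs with at least 20 reads, chi-square per degree of freedom was 1.44 to 2.14 within groups. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.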

Results

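RNA was measured in brain tissue of 3 wild boars and 3 Rongchang domestic pigs, as TPM of 21280 protein-coding genes and of 11375 circRNAs. Between 17862 and 18497 genes were above 0 per library. The recovered back-splice reads ranged from 33644 to 73089 per library, with a median of 11 reads per circRNA over the 6 libraries. Every comparison below sets wild boar against domestic pig, which also sets new libraries labelled brain against re-analysed ones labelled cerebrum.

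Protein-coding TPM summed to 23.8% ± 6.96 of 1000000 in wild boar and 33.3% ± 8.92 in domestic pig (SD, n = 3 each; exact permutation p = 0.2; 0.225 after Benjamini-Hochberg adjustment over 9 such comparisons). The circRNA TPM sum was 2048 ± 65.7 in wild boar and 3049 ± 276 in domestic pig (SD, n = 3 each), with every domestic pig library above every wild boar library (exact permutation p = 0.1, the smallest possible; adjusted 0.225). Set against the protein-coding sum, circRNAs made 0.909% ± 0.253 in wild boar and 0.955% ± 0.235 in domestic pig (exact permutation p = 0.8, n = 3 each; adjusted 0.8). Mitochondrially encoded genes took 16.7% ± 2.53 of the protein-coding sum in wild boar and 21.4% ± 4.83 in domestic pig (exact permutation p = 0.2, n = 3 each; adjusted 0.225).

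**Figure D1:**
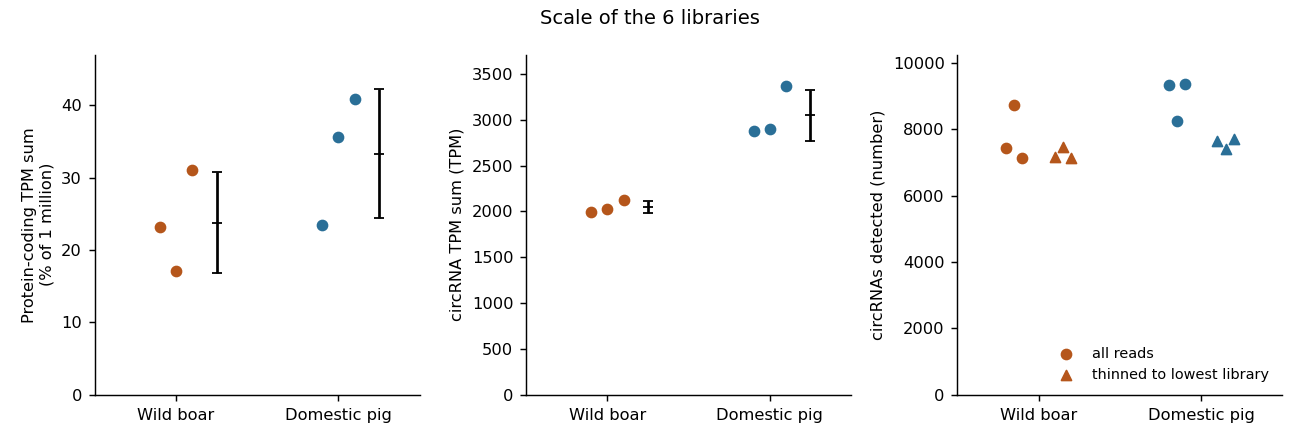
Protein-coding TPM sum in percent of 1000000 (left), circRNA TPM sum (middle) and circRNAs detected (right) in each library; points are libraries, bars are group mean ± SD, and triangles are numbers after thinning every library to 33644 reads. The circRNA sums of the 3 domestic pigs, 2880 to 3367 TPM, all lie above those of the 3 wild boars, 1994 to 2121 TPM.

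The first question was which protein-coding genes differ between wild boar and domestic pig brain. HBB, a beta-type globin of red blood cells, was higher in wild boar, at 619.7 ± 121.2 TPM against 189.8 ± 102.9 (SD, n = 3 each; log2 fold change 1.81, SE 0.40, limma adjusted p = 0.00134). S100A4, a calcium-binding protein of motile and stromal cells, and CEBPD, an inflammation-induced transcription factor, were also higher, by log2 1.70 (SE 0.33) and 1.37 (SE 0.33). NTS, which encodes the neuropeptide neurotensin, was lower, at 0.374 ± 0.0917 TPM against 9.15 ± 6.58 (log2 fold change -2.69, SE 0.33, limma adjusted p = 5.3e-13). DCAF16, a ubiquitin ligase subunit, was lower by log2 -2.46 (SE 0.35). On deposited TPM limma pooled the variance almost wholly over genes of like level, so S100A4, CEBPD and NTS share an SE of 0.33. These SE and p-values therefore do not measure the spread of a single gene between animals. After rescaling, where a gene's own spread counts more, NTS had a limma adjusted p of 0.00548 (SE 0.31).

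On deposited TPM, 188 of 11752 genes passed, 16 higher in wild boar and the rest lower, and 2091 had an unadjusted p under 0.05. The median log2 fold change of all genes was -0.41. After median-ratio rescaling, which sets that median to 0.00, 2303 genes passed, 1009 higher and 1294 lower, and 163 of the 188 were among them with the same sign. The lower share was 91.5% before and 56.2% after rescaling.

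After rescaling, HBB was higher by log2 2.32 (SE 0.44, limma adjusted p = 0.0129) and S100A4 by 2.06 (SE 0.48). MFAP5 and MGP, proteins of the extracellular matrix, were higher by 1.72 (SE 0.51) and 1.57 (SE 0.33). The ribosomal protein gene RPS20, the mitochondrial RNA-binding protein gene SLIRP and the DNA polymerase subunit gene POLE4 were higher by 1.63 (SE 0.30), 1.56 (SE 0.16) and 1.48 (SE 0.13). RAMP3, a receptor-modifying protein, CEBPD, SAL1, ZNF883 and C12orf75 were higher by 1.37 to 1.72. Of these 12, RPS20, MGP, SLIRP, POLE4, SAL1, RAMP3, ZNF883 and C12orf75 had not passed on deposited TPM, where their changes were 0.91 to 1.14.

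The 12 lower genes after rescaling included LUC7L3, a splicing factor gene, at 7.26 ± 2.02 TPM in wild boar and 33.2 ± 6.29 in domestic pig (SD, n = 3 each; rescaled log2 fold change -1.60, SE 0.12, limma adjusted p = 0.00122). PNISR, PRPF39, CLK1 and SRSF11, also linked to splicing, were lower by -1.59, -1.35, -1.24 and -1.15, each with an SE of at most 0.18; none of the fixed lists was one of splicing genes, so no list test covers them. TTC14, WSB1, CCDC18 and HFM1 were lower by -1.52, -1.26, -1.25 and -1.32. SLC17A6, a vesicular glutamate transporter found mostly outside the cortex, was lower at 3.03 ± 1.39 TPM against 10.6 ± 3.1 (rescaled log2 fold change -1.16, SE 0.18, limma adjusted p = 0.00736). NTS and DCAF16 were lower by -2.35 and -2.07.

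Leaving out 1 library on deposited TPM gave between 58 calls (without wild boar 1) and 665 (without domestic pig 1); without wild boar 2, domestic pig 2 and domestic pig 3 the counts were 113, 64 and 68. NTS, DCAF16, LUC7L3 and PNISR passed without any 1 library, whereas HBB missed the threshold without wild boar 1 (adjusted p = 0.0937) or domestic pig 2 (0.209), and of the 15 genes named on deposited TPM 5, 6 and 7 passed without wild boar 1, domestic pig 2 and domestic pig 3. S100A4 missed it without wild boar 1 (0.0899), and CEBPD without wild boar 1 (0.0708), wild boar 3 (0.0531) or domestic pig 3 (0.180). MFAP5 rested on wild boar 1, without which it was at log2 0.71 on deposited TPM (adjusted p = 0.664), against 1.38 with all libraries, and it missed the threshold without domestic pig 1 (0.0541) or 2 (0.0658). SLC17A6 missed it without wild boar 1 (0.0958), wild boar 2 (0.0925), domestic pig 2 (0.276) or domestic pig 3 (0.164). Without the filter on low values 6 genes passed, none of them named here. Globin, ribosomal protein and mitochondrial genes have near-identical copies whose reads the counting could split, so their levels are uncertain.

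**Figure D2:**
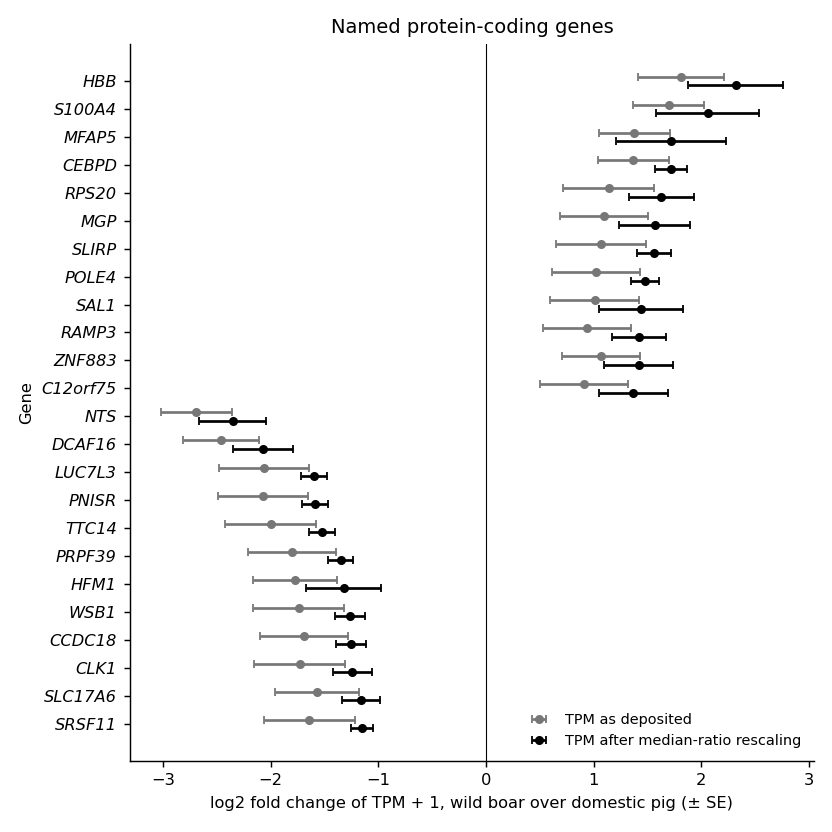
Log2 fold change of TPM + 1, wild boar over domestic pig, with its standard error, for the 24 genes named after rescaling; grey points are deposited TPM and black points are rescaled TPM. HBB stands highest at 2.32 and NTS lowest at -2.35 after rescaling, and every rescaled point lies to the right of its deposited one.

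The fixed gene lists asked which pathways and cell types moved. After rescaling 2303 of all 11752 genes passed, so a list can hold some passing members by that share alone. Cytosolic ribosomal protein genes and nuclear-encoded oxidative phosphorylation genes stood higher in wild boar relative to other genes on both scalings. Of 45 ribosomal protein genes, 6 passed after rescaling, all higher, and 39 did not; adjusted over the list alone, 4 passed. RPS15, RPS20, RPS29 and RPL38 were higher by log2 1.25, 1.63, 1.07 and 0.77. On deposited TPM 0 of the 45 passed, over all genes or adjusted over the list alone, and the list's median was -0.16 although its test pointed up. The list's camera adjusted p was 3.2e-04 on deposited and 8.5e-04 on rescaled TPM; with an estimated correlation the adjusted p was 0.979 and 0.971.

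Of 40 nuclear-encoded oxidative phosphorylation genes, 9 passed after rescaling, all higher (10 adjusted over the list alone), among them NDUFA2, NDUFA6, NDUFC2 and NDUFV1, subunits of respiratory complex I, by log2 0.88, 0.68, 0.65 and 0.52. On deposited TPM 0 of the 40 passed and the median was -0.19. The camera adjusted p was 0.00594 and 9.5e-05 after rescaling; with an estimated correlation the adjusted p was 0.979 and 0.971. The list of 13 mitochondrially encoded genes went the other way on deposited TPM, with a median of -0.75, 1 gene above 0 (ATP8, 0.71, not passing) and a camera adjusted p = 0.00916 (adjusted p = 0.979 with an estimated correlation). ND3 and COX2 passed, lower by -1.54 and -1.09, 11 of 13 did not pass, and 6 passed adjusted over the list alone. ND3 missed the threshold without wild boar 1 (adjusted p = 0.260) or domestic pig 3 (0.0523), and COX2 without wild boar 1 (0.664), wild boar 2 (0.122), domestic pig 2 (0.279) or domestic pig 3 (0.182). After rescaling 0 of the 13 passed, the median was -0.24, ATP8 was at 1.22 and the list was not called (adjusted p = 0.685). On deposited TPM it was also not called without wild boar 1 (adjusted p = 0.493) or domestic pig 2 (0.216).

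Markers of mural cells and fibroblasts, the contractile and collagen-making cells of vessel walls, stood higher relative to other genes on deposited TPM (camera adjusted p = 9.4e-04; adjusted p = 0.979 with an estimated correlation). Of these 10 genes 0 passed on deposited TPM by limma, over all genes or adjusted over the list alone. After rescaling the list missed the threshold (adjusted p = 0.0726), and TAGLN and ACTA2, smooth muscle genes, were higher by log2 1.05 (SE 0.25) and 1.11 (SE 0.33), against 0.59 and 0.64 on deposited TPM, with 8 of 10 not passing and 3 passing adjusted over the list alone. All 4 tested genes of the red blood cell list passed after rescaling, HBB by 2.32, AHSP and ALAS2 by 1.19 each and HBM by 1.03. On deposited TPM HBB and AHSP passed, AHSP by 0.93 and not without wild boar 1 (adjusted p = 0.662), domestic pig 2 (0.730) or domestic pig 3 (0.215). That list was too small for a list test. Of 7 endothelial markers, only CLDN5, a tight junction gene, passed after rescaling, by 1.27 (SE 0.18; 1 adjusted over the list alone), against 0.81 on deposited TPM (adjusted p = 0.275), and the list was not called (adjusted p = 0.509).

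Presynaptic vesicle release genes were called as higher relative to other genes on deposited TPM, although the list's median was -0.19, its mean -0.09 and 6 of 15 genes were above 0 (15 tested, camera adjusted p = 0.0141; adjusted p = 0.979 with an estimated correlation), with 0 single genes passing over all genes or adjusted over the list alone. After rescaling the list's adjusted p was 0.0913, and BSN, an active zone scaffold, and STX1A, a fusion protein, were higher by 0.94 and 0.38, STX1A against -0.10 on deposited TPM, and 0 passed adjusted over the list alone. Without domestic pig 1 the list's adjusted p on deposited TPM was 0.0836. The 5 tested striatal markers were called lower on deposited TPM (camera adjusted p = 0.00619; adjusted p = 0.979 with an estimated correlation). PENK, which encodes enkephalin, passed by -1.33, and all 5 passed adjusted over the list alone; after rescaling 0 passed and the list's adjusted p was 0.466. Without domestic pig 3 the list's adjusted p was 0.933 on deposited TPM and PENK was at -0.51 (adjusted p = 0.817). PENK also missed the threshold without wild boar 1 (-1.22, adjusted p = 0.578) or wild boar 2 (-1.07, adjusted p = 0.190).

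Neuron and glia markers went both ways after rescaling, and none of their lists was called. Their changes below are after rescaling. On deposited TPM only SLC17A6 of the genes named for these 5 lists passed, and CAMK2A, SLC17A7, NEUROD2, OLIG2, OLIG1, ALDOC and C1QA were at 0.35, 0.30, 0.08, 0.25, 0.04, 0.04 and 0.30, none of them passing. In the glutamatergic list CAMK2A, SLC17A7 and NEUROD2 were higher by log2 0.85, 0.80 and 0.51, while SLC17A6, NEUROD6 and RORB were lower by -1.16, -0.60 and -0.36, and the other 7 did not pass (4 higher and 3 lower adjusted over the list alone). In the myelin list ERMN, ASPA and UGT8 were lower by -0.76, -0.73 and -0.64, and 7 of 10 did not pass (3 lower and 1 higher adjusted over the list alone). In the list of oligodendrocyte precursors, cells of the same lineage, the transcription factor genes OLIG2 and OLIG1 were higher by 0.70 and 0.53, and 5 of 7 did not pass (2 higher and 2 lower adjusted over the list alone). In the astrocyte list ALDOC was higher by 0.54 and 8 of 9 did not pass (1 adjusted over the list alone). AQP4, of the next lowest p, was at -0.62 (limma adjusted p = 0.0708), and 6 of the 9 were above 0. In the microglial list C1QA was higher by 0.72 and 9 of 10 did not pass (0 adjusted over the list alone). Of 11 GABAergic markers 0 passed, over all genes or adjusted over the list alone, on either scaling. Of 11 immediate early genes, NPAS4 and NR4A3 passed as lower on deposited TPM (adjusted p = 0.00411 and 0.0426; 3 genes adjusted over the list alone) and missed the threshold after rescaling (adjusted p = 0.0902 and 0.0812). NPAS4 also missed it on deposited TPM without wild boar 2 (0.0886) or wild boar 3 (0.0566), and NR4A3 without any library except domestic pig 1.

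The lists are small, and 0 of 34 lists held with an estimated correlation on either scaling. On deposited TPM that correlation also takes in shifts of whole libraries. After rescaling it fell from 0.78 to 0.02 for the GABAergic list and from 0.72 to -0.03 for the presynaptic list. For the ribosomal list it was 0.67 and 0.74. The misses on deposited TPM therefore do not show that a list's own genes vary together. Fry's directional test also passed 0 on either scaling. It does not compare a list with other genes, so it does not decide whether the camera calls hold. Fry's mixed test, which asks whether genes of a list change in either direction, passed 0 lists on deposited and 20 on rescaled TPM. Without domestic pig 2, the adjusted p of the ribosomal and oxidative phosphorylation lists on deposited TPM was 0.109 and 0.248; after rescaling the ribosomal list was at 0.132 without domestic pig 2 and 0.0686 without wild boar 2, and at 0.189 with quantile scaling.

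**Figure D3:**
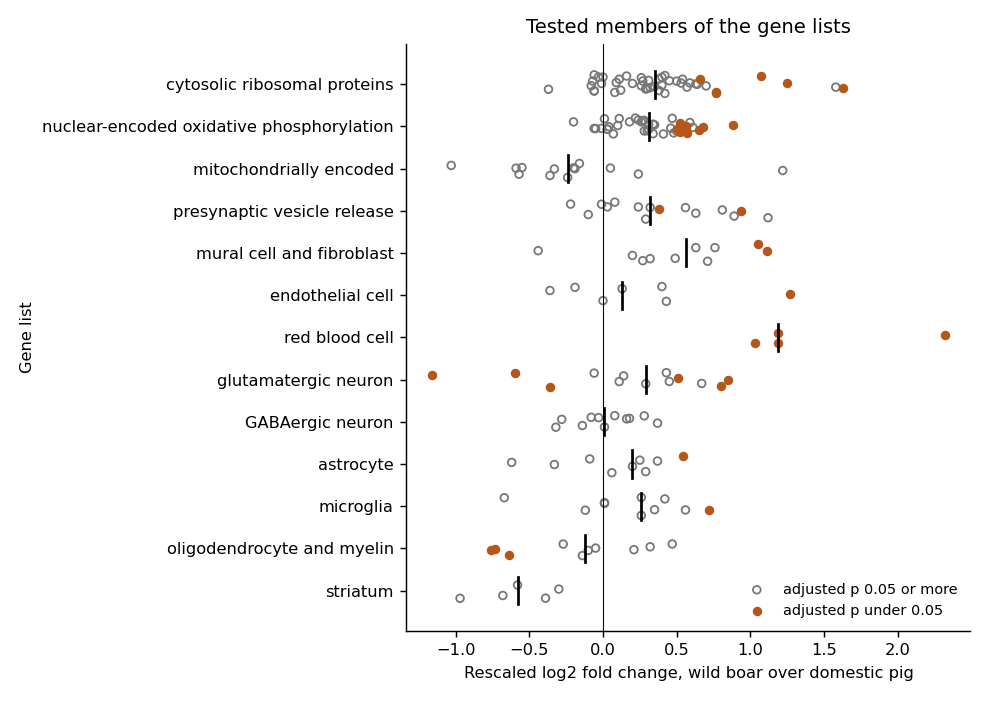
Rescaled log2 fold change, wild boar over domestic pig, of each tested member of 13 gene lists; filled points have an adjusted p under 0.05, open points do not, and black bars are list medians. The 4 red blood cell genes lie between 1.03 and 2.32, and the 13 mitochondrially encoded genes have a median of -0.24 against 0.31 for the 40 nuclear-encoded oxidative phosphorylation genes.

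The second question was which circRNAs the tissue of each breed holds. The 11375 circRNAs came from 18 autosomes and 3465 host genes, with a median length of 539 nt. No deposited circRNA lay on chromosome X, although the animals were labelled female, so X-linked circRNAs are outside these results. NBEA, a neuronal trafficking protein gene, and UBR3, a ubiquitin ligase gene, hosted 39 circRNAs each, and ATRNL1 and USP34 hosted 37 each. The most abundant of the deposited circRNAs came from TLK1, a kinase gene, and RIMS1, a presynaptic active zone gene. The TLK1 circRNA (ssc_circ_5038, chromosome 15, 77234646 to 77283482, minus strand, 267 nt) was at 25.2 ± 1.64 TPM in wild boar and 28.5 ± 4.21 in domestic pig. The RIMS1 circRNA (ssc_circ_891, chromosome 1, 52146557 to 52179177, plus strand, 516 nt) was at 22.8 ± 4.09 and 27.7 ± 6.23 TPM (SD, n = 3 each). Neither passed.

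Detected circRNAs numbered 7755 ± 843.8 per wild boar library and 8980 ± 640.9 per domestic pig library (exact permutation p = 0.2, n = 3 each). After thinning to 33644 reads the numbers were 7249 ± 194.2 and 7586 ± 160.4 (exact permutation p = 0.2, n = 3 each). Over the groups, 10015 circRNAs were found in both, 354 in wild boar only and 1006 in domestic pig only, and 3976 were found in all 6 libraries. In all 3 libraries of 1 group and 0 of the other were 34 wild boar and 225 domestic pig circRNAs. The 18 other choices of 3 libraries gave 17 to 209. With any 1 library left out these numbers were 52 to 127 and 326 to 626. They cannot fall, as the rule then asks for 1 library fewer, so they do not test how firm the counts are. The most read of the 34 came from PKD2 (20 reads), and those of the 225 from UNC13C, TMEM62 and GOSR1 (17 reads each), named after their values were seen. A circRNA at 0 was not detected at this depth and, with so few reads, is not shown to be absent.

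The third question was which circRNAs differ in level. Of 9709 tested, 13 passed on deposited TPM, all lower in wild boar, and 1408 had an unadjusted p under 0.05. The PCNX2 circRNA (ssc_circ_5555, chromosome 14, 57550062 to 57553314, plus strand, 388 nt) had 0, 1 and 0 reads in wild boar and 23, 10 and 23 in domestic pig, or 0.0132 ± 0.0229 against 1.10 ± 0.329 TPM (SD, n = 3 each; log2 fold change -4.32, SE 0.55, limma adjusted p = 0.00583). With 1 read in wild boar, that fold depends on the pseudocount. The SEPT7 circRNA (ssc_circ_6559, chromosome 18, 38110775 to 38132080, minus strand, 461 nt), from a septin cytoskeleton gene, was at 0.509 ± 0.154 against 2.61 ± 0.419 TPM (log2 fold change -2.29, SE 0.36, limma adjusted p = 0.0346).

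The other named circRNAs that passed came from MTHFD1L, a mitochondrial folate enzyme gene, CDS1, LDB2, PLA2R1, MLIP and MEF2C, a neuronal transcription factor gene. They were lower by log2 -2.60, -2.37, -2.02, -1.71, -1.58 and -1.49, each with an adjusted p of 0.0475. Among the 10 most abundant circRNAs, those of BMPR2, a growth factor receptor gene, and RASA2 also passed, lower by -1.24 and -1.15, and the other 8 did not. On deposited TPM no circRNA passed as higher. Those of the lowest unadjusted p in that direction came from LDLRAD3 (log2 fold change 2.33, SE 0.45), PKD2 (ssc_circ_11155; 4, 13 and 3 reads against 0, 0 and 0) and MYO9A (ssc_circ_1434; 8, 18 and 8 reads against 3, 0 and 0), and missed the threshold with adjusted p of 0.0536, 0.0536 and 0.0538. The LDLRAD3 circRNA (ssc_circ_2375, chromosome 2, 24996467 to 25013356, minus strand, 261 nt) had 18, 20 and 18 reads in wild boar and 2, 5 and 3 in domestic pig. Of 16 lists of circRNAs by host gene 0 were called, also with an estimated correlation, where the lowest adjusted p was 0.708; by fry's directional test, which does not compare a list with other circRNAs, 1 passed, the 11 circRNAs of nuclear-encoded oxidative phosphorylation genes (median -0.56, adjusted p = 0.0292), and 0 of those 11 passed singly. After dividing the circRNA values by the gene factors 0 passed that test (lowest adjusted p = 0.941). Fry's mixed test passed 4 circRNA lists on deposited TPM and 1 after dividing by the gene factors.

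These calls depended on scale: the median log2 fold change of all circRNAs was -0.45, and rescaling the circRNA values gave 2 calls, the LDLRAD3 circRNA higher (2.87, SE 0.44, adjusted p = 0.0362) and the PCNX2 circRNA lower (-3.96, SE 0.56, adjusted p = 0.0333). The circRNAs of SEPT7, MTHFD1L, CDS1, LDB2, PLA2R1, MLIP and MEF2C were then at -1.72, -2.09, -1.82, -1.46, -1.12, -0.99 and -0.90, and those of BMPR2 and RASA2 at -0.64 and -0.55, with adjusted p from 0.234 to 0.450, so none of these passed. Dividing by the gene factors left 0 (701 with an unadjusted p under 0.05). Voom on recovered reads, which sets circRNAs against the back-splice total, called 29, of them 25 higher. The higher ones included those of LDLRAD3 (ssc_circ_2375), PKD2 and MYO9A, with voom adjusted p of 3.9e-04, 0.00105 and 7.2e-04. The lowest voom adjusted p, 2.0e-05, 5.6e-05 and 2.5e-04, were of circRNAs from SV2B, RERE and NALCN, all higher. That of RERE had 631 reads in wild boar 2 against 96 and 97 in wild boar 1 and 3. Of the 13, 3 were also called by voom, as lower, those of PCNX2, SEPT7 and PLA2R1. On deposited TPM, without any 1 wild boar library 1 circRNA passed, that of PCNX2, and without any 1 domestic pig library 0 passed.

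**Figure D4:**
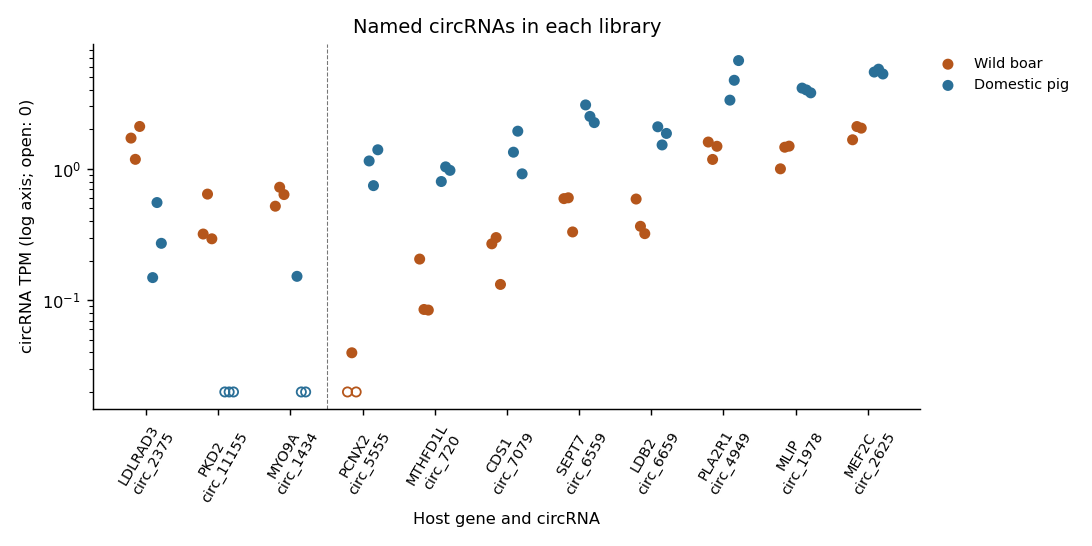
TPM (log axis) of the 11 circRNAs named for their change in each library; filled points are libraries above 0 and open points at the bottom are libraries at 0. The 3 circRNAs left of the dashed line missed the threshold and the 8 to its right passed, and the PCNX2 circRNA was at 0 in 2 of the 3 wild boar libraries.

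The last question was whether circRNAs follow their host genes. Across 2778 host genes, the log2 fold change of the summed circRNA value correlated with that of the protein-coding gene (Pearson r = 0.237, Spearman rho = 0.242), described across genes, which are not independent replicates. The other splits of the 6 libraries gave r from 0.019 to 0.169. The medians were -0.52 for circRNAs and -0.61 for host genes, and both changes lay on the same side of these medians in 59.3% of host genes, against 50% for unrelated changes. Without wild boar 2, r was 0.163.

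Set against the host gene, the circRNAs of CDS1 (ssc_circ_7079), MTHFD1L (ssc_circ_720), LDB2 (ssc_circ_6659) and MLIP (ssc_circ_1978) had log2 changes of the ratio of -1.55, -1.49, -1.41 and -1.12. Those of MEF2C (ssc_circ_2625), PLA2R1 (ssc_circ_4949) and LDLRAD3 (ssc_circ_2375) were at -0.59, -0.45 and 2.55. None passed: of 8665 circRNAs with a tested host gene, 0 were called by limma, 593 had an unadjusted p under 0.05, and the lowest adjusted p was 0.141. The median change of the ratio was 0.24. A circRNA pseudocount 4 times as large gave 25 calls, 24 of them higher. That setting pulls circRNA changes toward 0 and leaves host gene changes, with a median of -0.61, as they were. Calls as higher can follow from it and do not show a larger circular share in wild boar.

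**Figure D5:**
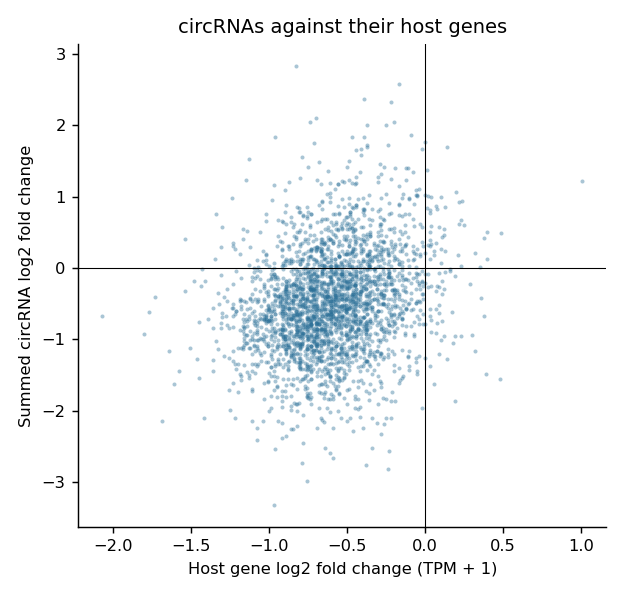
Log2 fold change of the summed circRNA value against that of the protein-coding host gene (TPM + 1), wild boar over domestic pig; each point is 1 of 2778 host genes. The cloud leans weakly upward (Pearson r = 0.237) and lies mostly below 0 on both axes, with medians of -0.61 and -0.52.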

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

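The voom, gene-factor, 20-read and table-sum settings and all settings within the rescaled fits were chosen after seeing the data. Pseudocounts of 0.1 and 5 gave 189 and 174 genes against 188, and a fold limit stayed within 1.5 times. The number of protein-coding genes called became 6 without a filter, 49 at TPM of at least 5, 285 without the trend and 9518 with array weights, whose fit did not converge. Scaling gave 2303 (median ratio), 2368 (1013 higher, 1355 lower; quantile), 2123 (585 higher, 1538 lower; without mitochondrial and top 20 genes) and 1146 (503 higher, 643 lower; table sum). Leaving out 1 library gave 58 to 665 genes, and 784 to 2195 against 2303 after rescaling: 784, 821, 863, 1060 and 1472 without wild boar 2, wild boar 3, domestic pig 1, wild boar 1 and domestic pig 3. The 6 lists became 2, 1, 3 and 3 under these scalings, 0 with an estimated correlation and 3 to 7 without 1 library. Fry's directional test passed 0, but it asks another question, as it does not compare a list with other genes. The 2 lists after rescaling became 0 with an estimated correlation and 1 to 4 without 1 library. The 13 circRNAs became 30 and 1 with a pseudocount 4 times and 0.5 times as large, 154 above 0 in all 6 libraries, 6 above 0 in any, 2 after rescaling, 0 over gene factors, 39 with at least 20 reads, 29 by voom, 0 to 1 without 1 library and 150 when summed per host. After the host gene, 0 became 25 with the larger pseudocount, which shrinks only the circRNA changes, and 3 above 0 in all 6. CircRNAs of 1 group alone numbered 52 to 127 (wild boar) and 326 to 626 (domestic pig) without 1 library, where they cannot fall. The circRNA and host correlation was 0.272 for well-measured hosts and 0.163 to 0.256 without 1 library. Beyond the number of samples or features tested, the cause was not tested.

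Replicate numbers did not pair the animals: same-number correlations of deviations were 0.10, -0.04 and -0.01 for genes and 0.00, 0.01 and 0.00 for circRNAs. With a replicate block 70 genes were called, 1250 after rescaling, 21 circRNAs, and 2 circRNAs after the host gene.

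Among single named genes, 13 values turned direction, none called on deposited TPM. STX1A, CRHBP and SGK1 were 0.38, 0.41 and 0.46 after median-ratio and 0.40, 0.43 and 0.47 after quantile scaling. With array weights TYROBP, CDH5, NPY, ZBTB16, EGR3, FOSL2 and ALDOA were -0.34, -0.22, -0.32, -0.44, -0.31, -0.32 and -0.40. Of 24 named genes called on deposited TPM, 18 lost their call without wild boar 1, 15 each without domestic pig 2 or 3, and 24 without a filter. Of 10 named circRNAs called, 9 lost their call after rescaling and 10 over gene factors. The 24 genes named after rescaling kept 19 to 21 calls there without 1 library. The planned negative binomial count tests were not run. In simulation 0% of circRNA changes of 2 log2 units were recovered, although some smaller real ones passed. Missing calls therefore say little about changes of that size.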

Other observations

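The tests below were chosen after the results were seen, except that of gene length, whose bound was set before its value.

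The fixed lists described here each held changed genes after rescaling, and none of them was called. As 2303 of all 11752 genes passed after rescaling, most lists of this size would hold some passing members. The counts below therefore do not mark these lists as changed. In the list of hosts of circRNAs abundant in mammalian brain the genes that passed included UNC13C, SMARCA5 and HIPK3, lower by log2 -0.99, -0.47 and -0.36 (2 lower adjusted over the list alone; list adjusted p = 0.0913). In the stress axis list PER1, CRHBP and SGK1 were higher by log2 0.57, 0.41 and 0.46, against 0.18, -0.04 and -0.03 on deposited TPM. PER1 and SGK1 are glucocorticoid-responsive, and CRHBP encodes a binding protein of corticotropin-releasing hormone. In that list 7 of 10 did not pass (4 higher adjusted over the list alone). Among neuropeptide genes CCK, NPY and CORT, made by cortical neurons, were higher by 0.80, 0.53 and 0.50, against 0.31, 0.06 and 0.27, and 9 of 12 did not pass (3 adjusted over the list alone). Among clock genes TEF and PER1 were higher by 0.57 each, against 0.10 and 0.18, and CIART, CLOCK and NR1D2 were lower by -0.64, -0.44 and -0.43 (4 higher and 4 lower adjusted over the list alone). In the hypoxia and glycolysis list ENO1, ALDOA and HK2 were higher by 0.98, 0.64 and 0.47, against 0.48, 0.14 and 0.24, and VEGFA was lower by -0.55 (4 higher and 2 lower adjusted over the list alone). Of the domestication candidates MITF and KIT, pigment cell genes, were lower by -0.52 and -0.50 (2 adjusted over the list alone). Of 17 genes of circRNA making and turnover, the RNA-editing gene ADARB1 was higher by 0.50, against 0.06, and YTHDC1 lower by -0.40 (1 each adjusted over the list alone). On deposited TPM only UNC13C of the genes in this paragraph passed by limma (-1.45, adjusted p = 0.0316), and not without wild boar 1 (0.328), wild boar 2 (0.102), domestic pig 2 (0.403) or domestic pig 3 (0.684).

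Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. On deposited TPM 2 of the 10 splits called as many genes (real 188, highest other 6094). The split with 6094 set wild boar 1, wild boar 2 and domestic pig 1 against the rest. These are the 3 libraries of the lowest protein-coding TPM sums, so it points to a structure of the samples in scale. After rescaling 1 split called as many (real 2303, highest other 0). For circRNAs 1 split called as many (real 13, highest other 1), for voom 1 (real 29, highest other 4), and for circRNAs after the host gene 10 (real 0, highest other 0). For gene lists 9 splits called as many (real 6, highest other 10) and for circRNA lists 10 (real 0, highest other 1).

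Most genes called on deposited TPM were lower in wild boar. The authors' normalization, a scale taken over more than the listed genes, and a true difference in the share of protein-coding RNA cannot be told apart. The lower share of 56.2% after median-ratio rescaling follows from centring and would arise under both. The protein-coding share of the TPM scale did not separate the groups (exact permutation p = 0.2), which 3 libraries per group cannot decide. Breed cannot be told apart from source project and labelled tissue.

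Ribosomal protein and oxidative phosphorylation genes stood higher relative to other genes by camera at a preset correlation, a call lost with an estimated correlation (adjusted p = 0.979 on deposited and 0.971 on rescaled TPM). Gene length as the whole cause is not settled. Rescaled changes fell with genomic span across 9834 genes (Spearman rho -0.33). The median of the 72 members with a span (of 85) was 0.34. It stood at percentile 99.99 of 10000 random lists of matched span, whose central 95% was 0.09 to 0.26, and so above the bound set. Those random lists drew genes independently. The ribosomal and oxidative phosphorylation lists had estimated correlations of 0.74 and 0.50 after rescaling, so that band is too narrow. Genomic span is also not transcript length, which was not tested. Of the oxidative phosphorylation list alone only 27 of 40 had a span. More mitochondria as the whole cause would also raise mitochondrially encoded genes, whose median was -0.24, with ATP8 alone far above 0 at 1.22. A lower share of nuclear RNA in the wild boar libraries stays open. A list of genes taken to have transcripts retained in the nucleus had 24 tested members, with a median of -0.67. Of these, 19 were called lower and 0 higher (5 lower on deposited TPM). Gene TPM does not separate retained from exported transcripts, and no source for the list is given here. Its members are mostly splicing genes, 2 of them (CLK1 and SRSF11) also named for their change. The list was written after other splicing genes had been seen to be low. Lower expression of splicing genes and nuclear retention therefore cannot be told apart, and breed stays open as untested.

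Red blood cell genes were higher in wild boar. More vessels as the whole cause would raise endothelial markers by about as much as the red blood cell genes (median 1.19), and the median of 7 was 0.13 (SE of members 0.2). CLDN5 at 1.27 (0.81 and not called on deposited TPM) and the vessel-wall list, with a rescaled median of 0.56 and TAGLN and ACTA2 called, go with more vessels, so a part of it stays open. More blood left in the tissue stays open too: that all 4 tested genes passed restates the pattern, and the neutrophil genes S100A8 and LCN2, at 0.58 (SE 0.34, limma adjusted p = 0.247) and 0.57 (SE 0.23, limma adjusted p = 0.113) after rescaling, decide neither way. Slaughter, sampling and breed stay open as untested sources of a blood difference.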
